A study of Mus musculus with 6 samples.

How the data were processed

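Circular RNAs (circRNAs) were measured in whole ovaries of C57BL/6 mice, an inbred laboratory strain, at 2 ages. The groups were neonatal ovaries at postnatal day 5 (n = 3) and adult ovaries at 6 weeks (n = 3). A circRNA is a closed RNA loop made when a splice donor is joined back to an upstream acceptor, and it is read from the reads that cross this back-splice junction. Per the labels' protocols, 5 µg of total RNA was treated with RNase R, an exonuclease that digests linear RNA and spares circles, at 3 units per µg for 15 min at 37 °C. Libraries were then made from 1 µg of RNA with random hexamers, the second cDNA strand was removed with uracil DNA glycosylase so that strand was kept, and 150 nt paired-end reads were taken on an Illumina HiSeq instrument. RNase R digestion and random priming set which molecules could be read, so levels refer to RNase R-treated RNA. The labels do not say whether each library came from a separate animal or from pooled ovaries, so the authors' p-values measure the spread between these libraries, which may be technical in part.

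The submitters' processing notes name Bowtie 0.12.2, with no role given, and the GRCm38 mouse genome build. The circRNA caller, the filters and the gene annotation are not given in the sources used here. The authors deposited 2 tables of the same 27999 circRNAs, and 1 line of each was left out of what was analysed here. Per the file headers, the authors gave each circRNA a log2 fold change of a group named A over a group named B, from group means of FPKM (fragments scaled to length and depth), which is infinite where the mean of 1 group is 0. The deposited p-value and the adjusted p-value (headed FDR) come from a test that is not named in the sources used here. The deposited adjusted values differed by at most 1.52e-05 from a Benjamini-Hochberg adjustment over all circRNAs. The 489 circRNAs that the authors' deposited table marks as different were those with p under 0.05 and an absolute log2 fold change of at least 1, as checked on the file.

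The letters A and B match no sample label, and which age each letter stands for is not given in the sources used here. The 24 columns of values per library (12 in each table) and 2 columns of group means therefore went into no computed value, and no statement about age is made for either group. They had been looked at before they were set aside: the number of values above 0 and the hosts of the highest values in each column, the correlations between columns and the values of Egfr were seen. Circles of Cyp11a1, a host of the steroid and cholesterol synthesis list, were among the highest in 2 of the columns of group B. Depth per library is unknown for the same reason, and no interval or floor that needs it is given. Tests planned on junction counts per library (a quasi-likelihood test per circRNA and per host gene, competitive list tests, a test of circRNAs within host genes, and exact permutation tests of circRNAs and classes per library) were not run, nor were the other settings planned for them. The comparison rests on the authors' fold changes and p-values instead.

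Where only 1 library of 6 holds a value, an unequal-variance test gives p = 0.423 whatever the value is, and this is the most frequent p the authors deposited. The 17355 circRNAs at exactly this p (tolerance 1e-09) were taken as having a value in a single library, and the other 10644 as having values in 2 or more. Each exonic circRNA was placed on its named isoform in the GENCODE M21 annotation of GRCm38. Coordinates are the authors' own, counted from 1. Both ends fell on annotated exon ends for 26141 of 26144 exonic circRNAs, and 25828 were placed on the named isoform. Host genes were matched to current RefSeq symbols directly (7048 of 7411) or through an older symbol (313), and 50 were not matched. Genes are named as the authors' table names them.

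Fixed before the data were examined were 23 lists of host genes: oocyte genes, meiosis, piRNA pathway, granulosa cell genes, steroid and cholesterol synthesis, ovulation and corpus luteum, EGFR and ErbB signalling, PI3K, AKT, FOXO and mTOR signalling, TGF-beta, BMP and activin signalling, Hippo signalling, Wnt signalling, stroma and theca cell genes, extracellular matrix, endothelial cell genes, smooth muscle cell and pericyte genes, leukocyte genes, ovarian surface epithelium and mesothelium genes, oviduct and fat tissue genes, cell division, RNA splicing and circRNA formation, DNA methylation and chromatin regulators, hormone receptors, and much-studied circRNA host genes. Several lists share hosts. The largest overlap among tested hosts was 4 genes, between granulosa cell genes and hormone receptors (Esr2, Ghr, Igf1r and Nr5a2). The list tests themselves were chosen after that, with the high values of Cyp11a1 in group B already known. For each list, the share of circRNAs higher in group A was averaged over its hosts, among circRNAs with values in 2 or more libraries, and set against 10000 random lists of hosts matched on the number of circRNAs per host (a two-sided permutation test). The number of hosts with a marked circRNA in each direction was tested in the same way. Benjamini-Hochberg adjustment ran over the 23 lists. The smallest p that 10000 random lists can give is 0.0001, which becomes 0.0023 after adjustment when a single list reaches it. Host genes are not replicates, so these tests describe the deposited libraries and not the spread between animals.

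Pathways were tested with the authors' KEGG assignments by Fisher's exact test, among the 1154 hosts with a pathway and for the 110 pathways of at least 10 hosts. Introns beside circRNAs were compared with the other introns of the same isoform and the share of hosts where they were longer was set against 2000 random placements of circles with as many exons on the same isoforms (a two-sided permutation test, smallest p 0.0005). The placements replaced an earlier test against a ratio of 1, which a mean of both introns exceeds by itself, and were chosen after the data had been seen. Intervals on shares are exact 95% binomial intervals. They cover counting error only and treat circRNAs or hosts as independent.

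The rule fixed before the data were examined named circRNAs past an adjusted p, by level per age group and by differences within hosts. The first part named none with the deposited adjusted p, and the others were not applied, since they rest on values per library or per age. The 10 circRNAs of each direction with the smallest p among the marked ones, those of largest fold, and hosts with several marked circRNAs were therefore named, a choice made after their values were seen. The parts naming every circRNA of Egfr and up to 4 hosts of each list per direction were applied with the deposited p, and in each list a few of those hosts are given. Results for some of these hosts are not reported here.

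The list tests were tested on simulated data with 4327 hosts, lists of 20 hosts and 500 random lists per test. When 25% of the circRNAs of a list were higher in A against 70% elsewhere, 25 of 25 lists were recovered and 1 of 75 unchanged lists was called. When 25% of the circRNAs of a list were marked against 3% elsewhere, 24 of 25 were recovered and 1 of 75 unchanged lists was called. Shares shifted toward A and lists of fewer hosts were not simulated, and circles of a host were drawn independently. How often such lists would be missed is therefore not known. Alternatives with other thresholds on the deposited values and other sets of circRNAs were computed as well. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.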

Results

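The deposited catalogue listed 27999 circRNAs from 7411 host genes in RNase R-treated RNA of neonatal and adult mouse ovaries, with 3 libraries per age. Exonic circRNAs, which join exons of a host gene, made up 26144 of them (93.4%). The other 1855 (6.63%) were intronic circRNAs (ciRNAs), which lie within an intron. Noncoding host genes gave 139 circRNAs (0.496%). The hosts with the most circRNAs were Syne2, which encodes a nuclear envelope spectrin-repeat protein (42 circRNAs), the transcriptional corepressor gene Rere (40), and Itpr1, Nbas and Vwa8 (39 each). Itpr1 encodes an endoplasmic reticulum calcium channel, and its relative Itpr2 had 37. A single circRNA was listed for 2624 hosts (35.4%). The 607 hosts with 10 or more (8.19%) gave 32.5% of the catalogue.

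**Figure D1:**
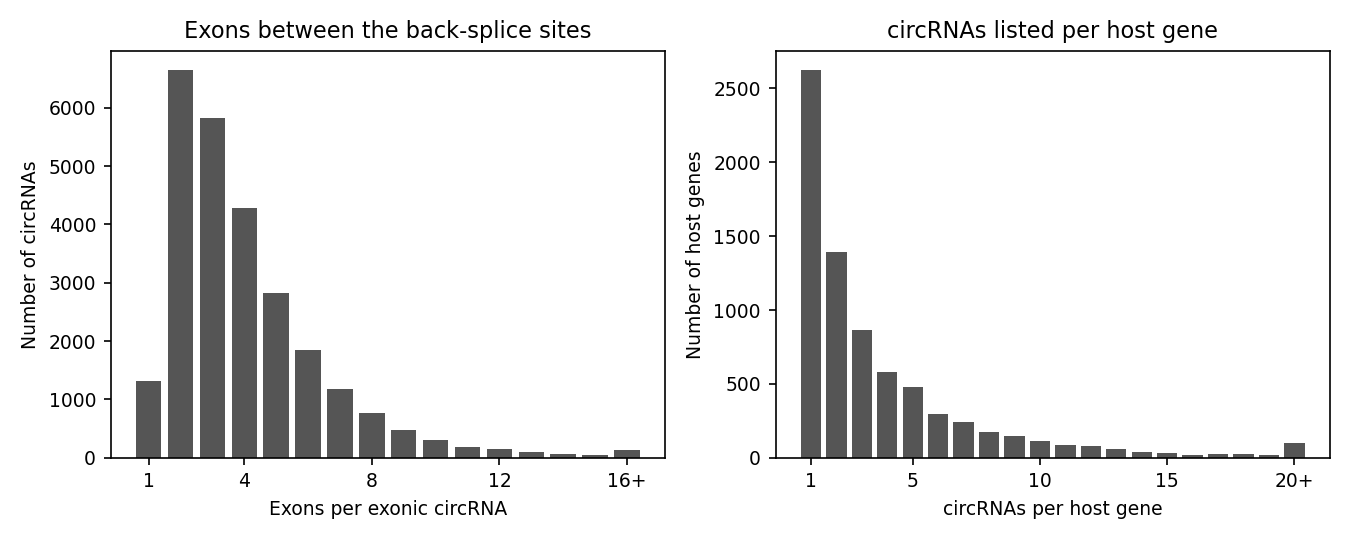
Left, number of exonic circRNAs by the number of exons between the back-splice sites, with 16 or more in the last bar. Right, number of host genes by the number of circRNAs listed for them, with 20 or more in the last bar. Circles of 2 exons were the most frequent (25.4%), and 35.4% of hosts had 1 circRNA.

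Most exonic circRNAs were short and lay within coding sequence. Those with 2 exons made up 25.4% and those with 3 exons 22.3%, and 20911 (80.0%) had 5 exons or fewer. The circRNA with the most exons, 47, came from Itpr1. The median genomic span of exonic circRNAs was 6732 nt (quartiles 2392 and 16322), and their median exonic length was 469 nt (quartiles 327 and 710). Intronic circRNAs spanned a median of 415 nt. Of the 25828 exonic circRNAs placed on their named isoform, 21550 (83.4%) held coding sequence only, 2705 (10.5%) held the start codon and 396 (1.53%) the stop codon. As that isoform is annotated, 281 (1.09%) held 3′ UTR only and 91 (0.352%) 5′ UTR only. The annotated 3′ UTR can cover internal exons, as for an Lphn3 circle of exons 9 to 12 of 25. Exon 2 was the most frequent first exon (6049 circRNAs, 23.4%), followed by exon 3 (12.4%) and exon 4 (9.66%). Exon 1 was part of only 20 of these circRNAs and the last exon of 9. Chromosome 2 held the most circRNAs (2233), and chromosome X held 636 (2.27%).

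Introns beside exonic circRNAs were longer than the other introns of the same isoform. The mean of both flanking introns had a median of 5617 nt, against 1968 nt for the median of the other introns. The flanking introns were longer in 6117 of 6821 hosts (89.7%, exact 95% interval 88.9 to 90.4), with a median ratio of 2.70. Random placement of circles with as many exons on the same isoforms gave 65.1% of hosts (central 95% 64.1 to 66.2) and a median ratio of 1.26 (permutation test, two-sided p = 0.0005, the smallest that 2000 placements can give). First introns are often long, and without circRNAs that start at exon 2 the share was 85.8%, against 59.0% by random placement. The upstream intron alone was longer in 85.0% of hosts (ratio 2.57) and the downstream intron alone in 80.4% (ratio 1.95).

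The study's design asks how ovarian circRNAs differ between neonatal and adult mice. The authors' deposited table makes this comparison between groups A and B, and which letter stands for which age is not given in the sources used here. Circles of Mctp1, Pcsk5, Akr1cl and Tpm1 had the smallest p among those higher in group B, and circles of AI314180, Ryr2, Celf2, Pard3 and Cul1 among those higher in group A. The authors' deposited table marked 489 circRNAs from 388 hosts as different, 343 higher in A and 146 higher in B. Among the marked circRNAs, 132 had values in A only and 49 in B only, and the 308 with values in both groups had a median absolute log2 fold change of 2.47 in the authors' deposited table. No circRNA passed an adjusted p of 0.05 in the authors' deposited table, where the smallest adjusted p was 0.425 and 545 circRNAs had an unadjusted p under 0.05. These 545 were 5.12% of the 10644 circRNAs with values in 2 or more libraries. The share that chance would give in that set was not computed. By the adjusted p, none of the circRNAs named here is set apart from chance singly.

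The smallest p of the authors' deposited table belonged to circRNA165 of Mctp1, which encodes a membrane protein with C2 domains. This circle of exons 7 and 8 of 21 (chromosome 13, 76756986 to 76759820, coding sequence) had a log2 fold change of -5.13 in the authors' deposited table, higher in B (p = 1.76e-05). A further Mctp1 circle in the authors' deposited table, circRNA4107, stood at -3.22 (p = 0.000344). Pcsk5, a proprotein convertase gene, had circRNA21107 (chromosome 19, 17675421 to 17714901, exons 4 to 7) in B only in the authors' deposited table (p = 3.04e-05). The aldo-keto reductase gene Akr1cl had 3 overlapping circles at log2 fold changes of -4.39, -3.88 and -2.95 in the authors' deposited table (p = 0.00046, 0.000703 and 0.000981). Mast4, which encodes a microtubule-associated kinase, stood at -1.89 (p = 0.000822) and Mmd2 at -4.17 (p = 0.000897) in the authors' deposited table. Intron 1 of the tropomyosin gene Tpm1 (chromosome 9, from 67032028 to 67032793) gave a ciRNA in B only in the authors' deposited table (p = 0.000158), listed again with a start 1 nt away.

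Among circRNAs higher in A, the authors' deposited table gave the smallest p to AI314180, with circRNA2343 in A only (p = 0.000151). Ryr2, which encodes a calcium release channel, followed in the authors' deposited table with circRNA84 (chromosome 13, 11769852 to 11785141, exons 24 to 27 of 105) at a log2 fold change of 1.78 (p = 0.000187). Circles of Celf2 (an RNA-binding splicing regulator, p = 0.00024), Cul1 (a ubiquitin ligase scaffold, p = 0.000386), Ehmt1 (a histone methyltransferase, p = 0.00114) and Asxl3 (p = 0.00126) had values in A only in the authors' deposited table. Pard3, a cell polarity gene, stood at 1.38 (p = 0.000272), the DNA primase gene Prim2 at 1.54 (p = 0.000586), the lipase-related gene Pnliprp2 at 4.14 (p = 0.000925) and Tspan18 4-fold higher in A (p = 0.000695) in the authors' deposited table. The largest folds among marked circRNAs with values in both groups of the authors' deposited table were those of Zfp385b (5.59), Cacna1d (5.28) and the noncoding gene Rmst (5.20 and 5.15) toward A. Toward B they were those of the thyroid hormone receptor gene Thrb (-5.60), Mctp1 (-5.13) and the malic enzyme gene Me1 (-4.64 and -4.42) in the authors' deposited table.

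**Figure D2:**
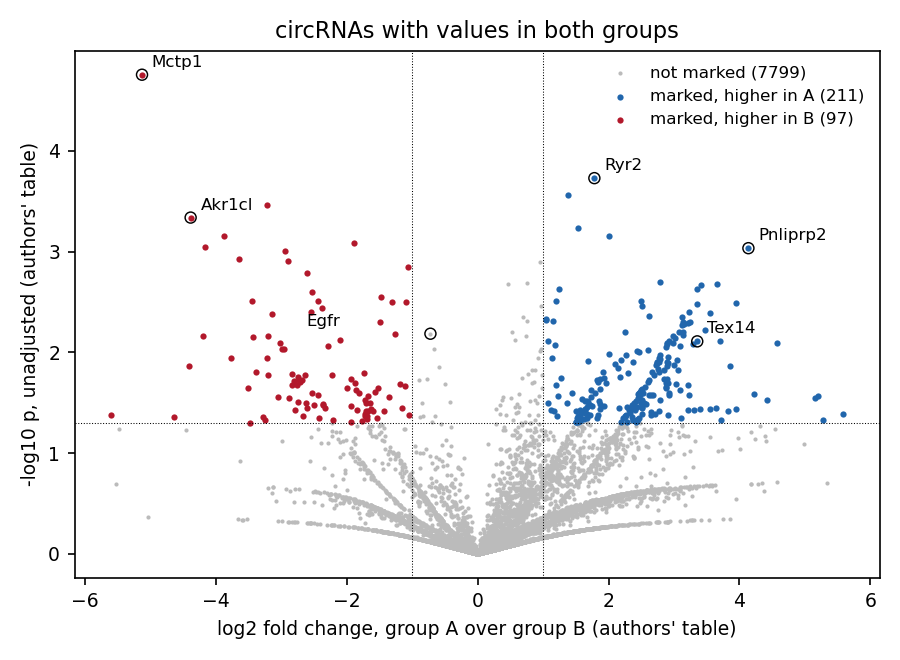
Each point is 1 of the 8107 circRNAs with values in both groups of the authors' deposited table, with its log2 fold change of A over B on the x axis and -log10 of its unadjusted p on the y axis. Blue and red points are the 211 and 97 circRNAs the authors marked as higher in A and in B, dotted lines mark p = 0.05 and absolute log2 fold changes of 1, and open circles mark a circRNA of the named host.

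Circles of the same host mostly lay on the same side. Of the 72 hosts with 2 or more marked circRNAs in the authors' deposited table, 50 had all of them higher in A and 21 all higher in B. Examples toward A were Lphn3, an adhesion receptor gene (5 circRNAs), the metalloprotease gene Adamts19, the tyrosine kinase gene Fer and Zfp407 (4 each), and Magi1, Pard3 and Mirg (3 each). Examples toward B were Crim1, which encodes a transmembrane protein that binds bone morphogenetic proteins (5), Me1 and Pcsk5 (4 each), and the cholesterol efflux gene Abca1, Akr1cl, Mctp1, Pvt1 and Sema5a (3 each). The log2 fold changes of the 5 Crim1 circles ran from -2.73 to -1.53 in the authors' deposited table. Only Sdccag8 had marked circRNAs on both sides in the authors' deposited table, circRNA3202 2.83-fold higher in A (p = 0.0496) and circRNA19581 5.04-fold higher in B (p = 0.0358). When directions were shuffled among marked circRNAs, a mean of 35.4 hosts and at least 22 had both directions (permutation test with 10000 shuffles, two-sided p = 0.0001, the smallest they can give). Circles of a host often shared a splice site, so they are not independent.

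More circRNAs were higher in group A than in group B. Of the 27999 circRNAs of the authors' deposited table, 13023 (46.5%) had values in A only, 6869 (24.5%) in B only and 8107 (29.0%) in both. Among the 10644 with values in 2 or more libraries, 7461 were higher in A (70.1%, exact 95% interval 69.2 to 71.0). Among those with values in both groups of the authors' deposited table, 5460 were higher in A (67.4%, interval 66.3 to 68.4), with a median log2 fold change of 0.42. The fold changes given for single circRNAs are not corrected for this shift toward A.

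The series title names a circular RNA of Egfr, the epidermal growth factor receptor gene, in granulosa cells. Which Egfr circle it means is not given in the sources used here, and the authors' deposited table lists 5, all on the plus strand of chromosome 11. The authors' deposited table gave circRNA434 (16881464 to 16883613, exons 14 and 15 of a 16-exon isoform, 249 nt of coding sequence) a log2 fold change of -0.72, 1.65-fold higher in B (p = 0.00653, adjusted p = 0.522), and did not mark it. The circles circRNA23775 (exons 2 and 3), circRNA20636 (exons 3 and 4) and circRNA22217 (exons 4 to 15) had a value in a single library, in B, and circRNA4759 (exons 24 to 27 of a 28-exon isoform) in a single library, in A (p = 0.423 for each in the authors' deposited table).

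**Figure D3:**
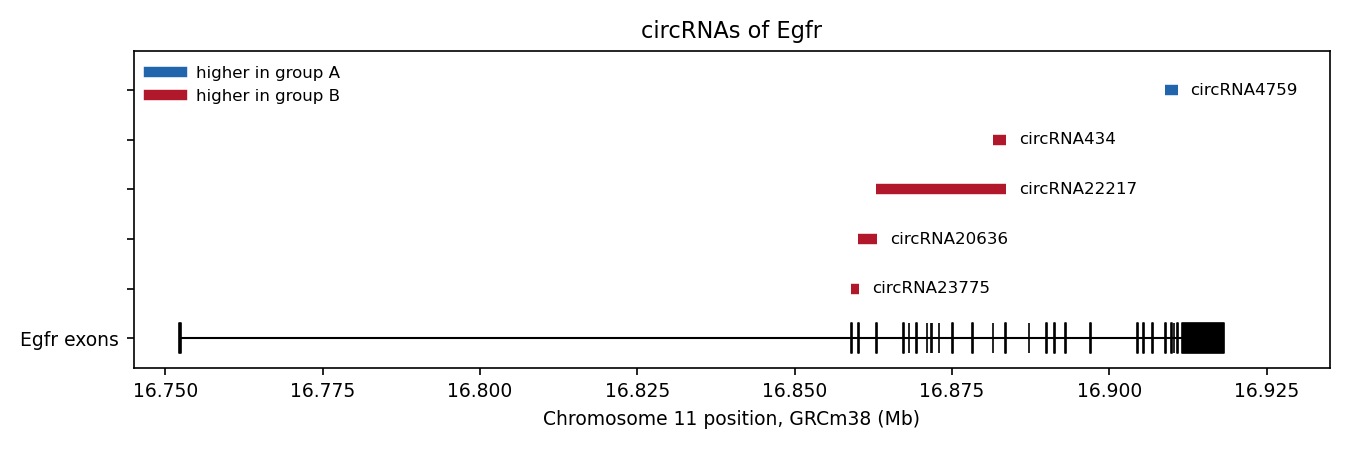
Map of Egfr on chromosome 11 (position in Mb, GRCm38), with the exons of a 28-exon isoform in black and the genomic span of each listed circRNA above them. Red circles are higher in group B and the blue one in group A; apart from circRNA434, each has a value in 1 library.

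Host genes of steroid and cholesterol synthesis stood apart from other hosts. On average 23.7% of their circRNAs were higher in A (19 hosts, 30 circRNAs), against 64.7% in matched random lists (central 95% 44.6 to 84.2, permutation p = 0.0001, adjusted p = 0.0023). For 14 of these hosts, all circRNAs with values in 2 or more libraries were higher in B in the authors' deposited table. Among these hosts were Lhcgr (the luteinizing hormone receptor), Cyp11a1 (the cholesterol side-chain cleavage enzyme), Cyp19a1 (aromatase), Hsd17b1, Scarb1 and Abca1. Only Abca1 (6 circRNAs), Lhcgr (2) and Scap (2) had more than 1 such circRNA, so for the others this was the direction of 1 circle. Lhcgr circRNA15020 stood at a log2 fold change of -5.48 (p = 0.0581) and Soat1 circRNA19521 at -1.64 (p = 0.157) in the authors' deposited table, neither of them marked. Abca1 alone had marked circRNAs, 3 of them, in the authors' deposited table, at -2.23 (p = 0.0169), -1.94 (p = 0.0185) and -2.72 (p = 0.0198). On the other side, circles of Acat1 (0.76, p = 0.268) and Stard3 (1.74, p = 0.31) were higher in A in the authors' deposited table. Among circRNAs with values in both groups the share was 28.6% over 14 hosts, and the adjusted p of 0.077 no longer passed. High values of Cyp11a1 in group B had been seen before the test was chosen. Without this host the share was 25% (unadjusted permutation p = 0.0005, the smallest that 2000 random lists can give). Cyp11a1 had 1 circRNA and weighed no more than any other host. Leaving it out therefore does not undo the effect of that look on the choice of test.

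Granulosa cell genes leaned the same way without passing the test. This lean is partly that of the same hosts, since the list shares Cyp19a1 and Hsd17b1 with steroid and cholesterol synthesis. Each of these had 1 circRNA with values in 2 or more libraries, higher in B. The circRNAs of granulosa cell genes were higher in A in 42.9% on average (18 hosts, permutation test, adjusted p = 0.0725). The authors' deposited table marked circles of 3 of these 18 hosts as higher in B, namely the nuclear receptor gene Nr5a2 (-2.54, p = 0.00399), the protein kinase A subunit gene Prkar2b (-2.28, p = 0.00869) and Greb1 (-2.66, p = 0.0424), against 0.404 hosts in random lists (permutation p = 0.0055, adjusted p = 0.127). Hormone receptors, which share Nr5a2 and other hosts with that list, had 52.1% higher in A (28 hosts, permutation test, adjusted p = 0.161). Circles of Esr1 (the estrogen receptor alpha gene, in B only, p = 0.0124) and Thrb (-3.52, p = 0.0228) were marked as higher in B in the authors' deposited table. Hosts of ovulation and corpus luteum had 51.4% higher in A (12 hosts, adjusted p = 0.361), with Runx2 at -3.21 (p = 0.00693) and Adamts9 at 1.72 (p = 0.0422) in the authors' deposited table.

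Hosts of the piRNA pathway list, named for a pathway that silences transposons in germ cells, carried more marked circRNAs higher in A than random lists. The authors' deposited table marked circles of 5 of 9 hosts as higher in A, against 0.493 in random lists (permutation p = 0.0001, adjusted p = 0.0023), and of none as higher in B. These were Gtsf1 (in A only, p = 0.00707 and 0.0276), Piwil4 (in A only, p = 0.0129), Tdrd1 (4.22, p = 0.0259), Mov10l1 (in A only, p = 0.0282) and Tdrd3 (1.75, p = 0.0338) in the authors' deposited table. Membership followed the list as fixed beforehand. Whether each member, such as Tdrd3, acts in the pathway was not checked, and the test was not run without it. Tdrd5 went the other way at -0.40 (p = 0.0848) in the authors' deposited table. The list's share of circRNAs higher in A was 88.9% (permutation test, adjusted p = 0.326). The central range of random lists reached 91.7%, so the test of shares had little room toward A. With values in both groups only 2 of the list's hosts had a marked circRNA (permutation test, adjusted p = 0.224).

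Other germ cell and dividing cell lists lay toward A without passing. For small lists the direction test had little room on that side. The central range of matched random lists already reached 97.6% for oocyte genes and 88.9% for meiosis. Not passing therefore does not speak against a shift toward A for these small lists. Meiosis hosts had 91.7% of circRNAs higher in A (12 hosts, adjusted p = 0.161), with Tex14, a gene of germ cell bridges, at 3.35 (p = 0.00778) and Tex15 at 2.89 (p = 0.0125) in the authors' deposited table. Oocyte genes had 92.9% (6 hosts, adjusted p = 0.326), and circles of Zp2 and Sohlh1 had values in A only in the authors' deposited table (p = 0.185 each). Cell division hosts had 84.9% (31 hosts, adjusted p = 0.0725), and 6 of them had a circRNA marked as higher in A against 2.50 in random lists (permutation p = 0.0234, adjusted p = 0.269). The authors' deposited table gave Prim2 1.54, Diap3 2.51 (p = 0.00347), the helicase gene Brip1 3.12 (p = 0.00447) and the kinesin gene Kif4 2.91 (p = 0.0126). Extracellular matrix hosts had 89.6% (24 hosts, adjusted p = 0.0725), with Fras1 at 3.66 (p = 0.00207) and the fibrillin gene Fbn2 at 1.71 (p = 0.0332) toward A, and the laminin gene Lama1 at -0.89 (p = 0.0189) in the authors' deposited table.

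Signalling lists lay within the range of random lists. EGFR and ErbB signalling hosts had 55.3% of circRNAs higher in A (25 hosts, adjusted p = 0.326), with the ubiquitin ligase gene Cblb at -1.72 (p = 0.0426) in the authors' deposited table. PI3K, AKT, FOXO and mTOR signalling had 72.6% (29 hosts, adjusted p = 0.78), with Depdc5 at -1.99 (p = 0.0227) in the authors' deposited table. TGF-beta, BMP and activin signalling had 66.2% (24 hosts, adjusted p = 0.948), with an Ltbp2 circle in A only in the authors' deposited table (p = 0.00168). Hippo signalling had 74.1% (28 hosts, adjusted p = 0.714), with a Strn3 circle in A only in the authors' deposited table (p = 0.0119). Wnt signalling had 77.7% (16 hosts, adjusted p = 0.473), with Lrp6 at 2.40 (p = 0.0351) and a Vangl1 circle in A only in the authors' deposited table (p = 0.00279).

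Markers of other ovarian and neighbouring cells also lay within that range. The shares higher in A, each with its permutation test, were 63.8% for stroma and theca cell genes (17 hosts, adjusted p = 0.901), 62.3% for endothelial cell genes (19 hosts, adjusted p = 0.901), 62.7% for leukocyte genes (15 hosts, adjusted p = 0.901) and 53.9% for smooth muscle cell and pericyte genes (18 hosts, adjusted p = 0.326). They were 67.0% for ovarian surface epithelium and mesothelium genes (10 hosts, adjusted p = 0.965) and 58.3% for oviduct and fat tissue genes (9 hosts, permutation test, adjusted p = 0.888). Emr1, a macrophage marker, stood at -2.44 (p = 0.00312), while circles of Arhgap31 (p = 0.00777) and Ccdc40 (p = 0.0192) had values in A only in the authors' deposited table. RNA splicing and circRNA formation hosts had 57.9% (36 hosts, adjusted p = 0.469), with Rbfox2 at 3.21 (p = 0.00509) and Sf3b3 at -1.20 (p = 0.0206) in the authors' deposited table. DNA methylation and chromatin regulators had 71.6% (55 hosts, adjusted p = 0.901), with Arid1b at 2.89 (p = 0.0136) in the authors' deposited table. Much-studied circRNA host genes had 72.5% (43 hosts, adjusted p = 0.888), with Slc8a1 in A only (p = 0.00273) and Crim1 at -2.73 (p = 0.019) in the authors' deposited table.

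**Figure D4:**
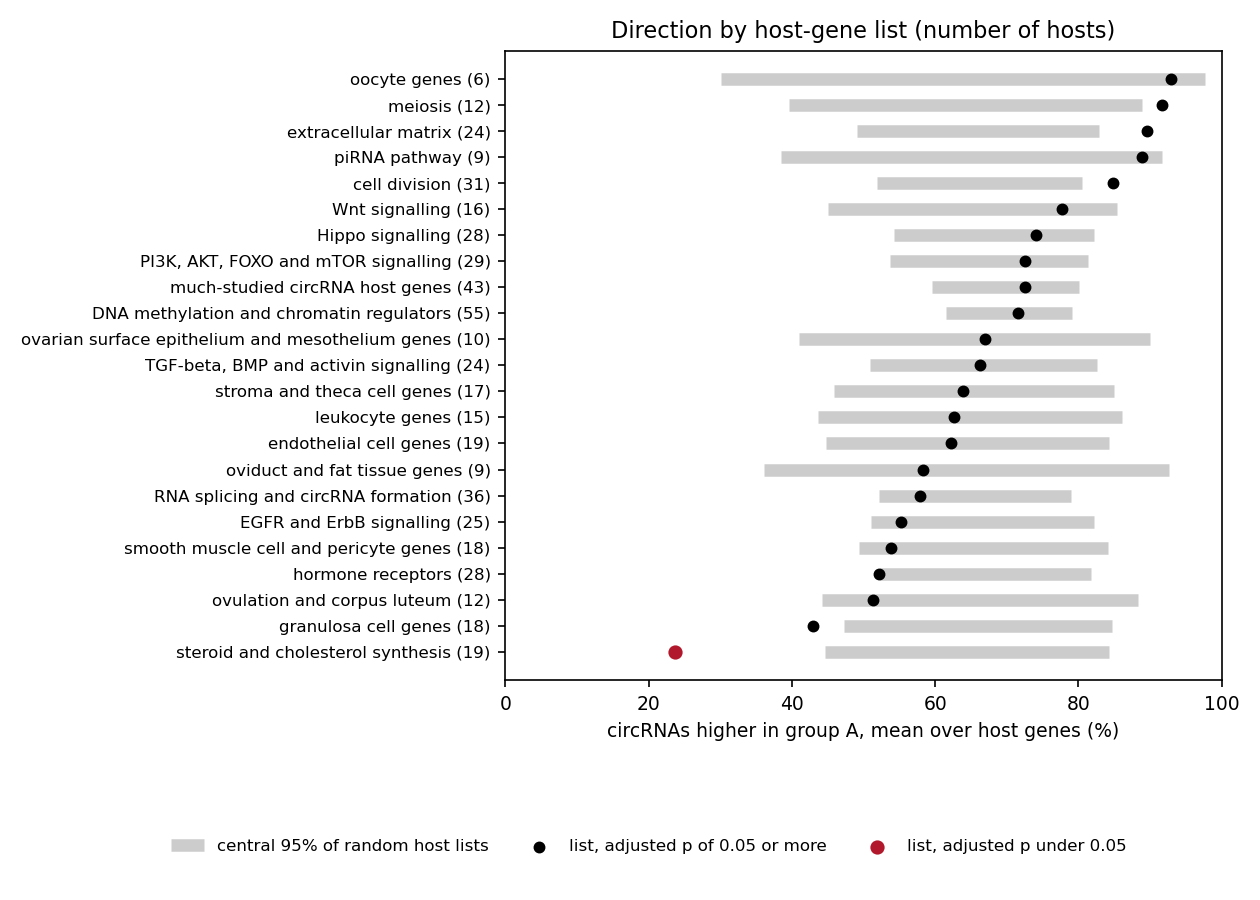
Share of circRNAs higher in group A (x axis, percent, mean over host genes) for each of the 23 host-gene lists, among circRNAs with values in 2 or more libraries, with the number of hosts in parentheses. Grey bars are the central 95% of 10000 matched random lists. Steroid and cholesterol synthesis, at 23.7%, was the list past an adjusted p of 0.05. Lists of few hosts had little room to pass toward A.

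Over all circRNAs, 0 circRNAs of any list passed an adjusted p of 0.05 in the authors' deposited table. Adjusted over the list alone, the counts from the authors' p-values were 2 for smooth muscle cell and pericyte genes (both Tpm1 entries, smallest adjusted p = 0.00998), 1 for RNA splicing and circRNA formation (Celf2, adjusted p = 0.0471) and 0 for each of the other lists. None of the 110 KEGG pathways passed for hosts of marked circRNAs in either direction (Fisher's exact test, adjusted p = 1 for each).

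Intronic circRNAs went against the general lean toward A. With values in 2 or more libraries, 43 of 166 intronic circRNAs were higher in A (25.9%, exact 95% interval 19.4 to 33.3), against 7418 of 10478 exonic ones (70.8%, Fisher's exact test, two-sided p = 3.21e-32). This p treats circRNAs as independent and does not measure the spread between libraries or animals. The authors' deposited table marked 14 intronic circRNAs, 13 of them higher in B, from 11 hosts, 10 of them higher in B. They lay in introns of Tpm1, the translation initiation factor gene Eif4g1, the oxysterol-binding protein gene Osbpl7, Acsbg1, Arhgef17, Gramd1b, the spectrin gene Sptan1, Sugp2, Trappc4 and 2310067B10Rik. Trappc4 stood at -1.88 (p = 0.0204) and Osbpl7 ciRNA4 at -1.15 (p = 0.036) in the authors' deposited table, and most of the others had values in B only. The marked ciRNAs of Tpm1, Eif4g1 and Osbpl7 are each a pair with ends 1 nt apart. In the authors' deposited table the Eif4g1 and Osbpl7 pairs have 1 member with values in B only and 1 with values in both groups, which for Eif4g1 stood at -2.62 (p = 0.0317). The marked intronic circRNA higher in A came from Ppan (in A only, p = 0.0286) in the authors' deposited table.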

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

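All alternatives given here were chosen after the data had been seen. None of those planned before (other scalings, filters on low counts, other models, a replicate block, thinning of reads, leaving out each replicate in turn) was run, because the columns of values match no sample, and for the same reason other splits of the libraries were not made. No paired analysis was possible because the columns carry no sample or replicate label that would pair the libraries of both ages. Of 30 alternatives over 7 results, 22 kept the direction and stayed close to the reported value or on the same side of the threshold. None reversed, but alternatives for the number of marked circRNAs and of lists had no direction to reverse. The others share many circRNAs with the main setting, so they are not independent of it. With a limit of p = 0.01 in place of 0.05, 146 circRNAs of the authors' deposited table were marked, 65.8% of them higher in A. With an adjusted p under 0.05 there were 0, against 545 at an unadjusted p under 0.05. With values in both groups 308 stayed marked; each of these limits takes fewer circRNAs by construction. The number of lists with a direction past the threshold was 5 over all circRNAs (steroid and cholesterol synthesis, granulosa cell genes, meiosis, piRNA pathway and cell division) and 0 with values in both groups, where cell division hosts with a circRNA marked as higher in A passed instead (permutation test, adjusted p = 0.0484); the cause was not tested. In that last set the steroid and cholesterol synthesis share was 28.6% (permutation test, adjusted p = 0.077, against 0.0023 over all circRNAs and over exonic ones), and 2 piRNA pathway hosts had a marked circRNA higher in A (adjusted p = 0.224, against 0.0023 to 0.0046), with fewer hosts tested. Introns beside circRNAs were longer in 80.4% to 85.8% of hosts under the alternatives, against 42.7% to 59.0% by random placement. Depth is unknown, so absence from a group cannot be told from too few reads.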

Other observations

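The list tests and the tests of depth, of the authors' scaling, of hosts counted once, of the marked intronic circRNAs and of circRNAs listed in 1 group only were chosen after the result was seen. Circles of noncoding hosts lay on both sides. Pvt1, a long noncoding RNA gene beside Myc, had 3 marked circRNAs in the authors' deposited table, at log2 fold changes of -2.90 and -3.44 and with values in B only. Mirg, a noncoding gene of the imprinted Dlk1 region, had 3 toward A in the authors' deposited table, at 2.27 and 1.60 and with values in A only. These genes were chosen after their values were seen.

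More circRNAs were higher in group A than in group B. A few hosts with many circRNAs do not account for this, since 68.5% of hosts with unequal numbers had more circles higher in A (4492 against 2066 hosts, interval 67.4 to 69.6). Greater depth in A alone would leave circRNAs with values in both groups balanced, but 67.4% of them were higher in A, and 1 scaling factor would leave circRNAs listed in 1 group only balanced, but 65.5% of those were in A. A mix of depth and scaling could still give both and stays open, untested. Unequal digestion of linear RNA between the groups was not tested for this pattern either. The age difference of the design also stays open, as the letters are not matched to ages.

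Intronic circRNAs were more often higher in group B. The 166 with values in 2 or more libraries came from at least 148 hosts, so they were not the product of a few hosts with many ciRNAs. Counted once per host, 27.0% of the 148 hosts with a majority direction were higher in A. With so few ciRNAs per host, this count had to lie near the share of single ciRNAs and is no separate test. A single library of B rich in intronic circRNAs would not mark them more often on the B side than exonic ones. Marked hosts did differ (Fisher's exact p = 2.32e-05, counted over hosts and not libraries). For the unmarked ones, a single library of B stays open. Of those higher in B with values in 2 or more libraries, 48.2% had p under 0.3 (53 of 110). This decides nothing, since leaving out single-library circRNAs puts all 45 listed in B only under that limit. Unequal digestion of linear RNA, which could leave intron fragments in 1 group, also stays open, untested, and no biological explanation was tested.

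Circles of steroid and cholesterol synthesis hosts were more often higher in group B. With 1 host left out the share lay between 19.4% and 25%, and the largest unadjusted permutation p was 0.0015 (2000 random lists each). Each of the 19 hosts weighs the same in this share, so no single host could have brought it into the range of random lists. The outcome was thus fixed by the weighting, and the test adds no evidence of its own. Circles listed in 1 group only were not the whole of it, since the share with values in both groups was 28.6% (unadjusted permutation p = 0.0035, adjusted p = 0.077). A single library of B stays open. Of circles higher in B with values in 2 or more libraries, 54.5% had p under 0.3 (12 of 22), among them all 6 listed in B only. The same restriction had left out circles with a value in a single library, so this decides nothing. No biological explanation was tested, as linear RNA was not measured here and the ages are not matched to the letters.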
